A study of Rattus norvegicus with 50 samples.

How the data were processed

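Total RNA from distal airway and alveolar tissue of male Fischer F344 rats was measured on 50 Affymetrix HT rat expression arrays, 1 animal per array. The rats had inhaled nickel subsulfide (Ni3S2) aerosol at 0, 0.04, 0.08, 0.15 or 0.60 mg/m3 for 6 hours a day on 5 days a week, for 1 or 4 weeks, which gave 10 groups of 5 arrays. Each group held 13 animals, of which 5 were used for lavage and histology and 8 for expression and lung nickel burden. The 5 animals of a group with the best RNA were put on arrays. Tissue was dissected from the right caudal lobe, RNA was extracted with Trizol and a column kit, and 50 to 150 ng of total RNA, depending on the yield, was labelled with a 3' in vitro transcription kit. Lavage, histology and nickel burden values were not used here.

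The deposited values are log2 intensities. Per the submitters' processing notes they were made with RMA in Partek; versions, the arrays that were normalised together and scan dates are not given in the sources used here. The table held 31042 probe sets for all 50 arrays, with values from 2.22 to 13.8 and array medians from 5.25 to 5.61. Any 2 arrays differed in at least 31031 probe sets. No value was transformed, filtered or normalised again before the main comparisons. The number of arrays, 5 per group, limits the precision.

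Probe sets were matched to genes by the platform's gene table. There, 19063 probe sets carried 1 gene symbol, 572 carried several and 11407 carried none. Probe sets without exactly 1 symbol were left out, so genes reached only by them were not tested. For the 3985 genes with more than 1 probe set, the one with the highest mean over all arrays was used, which left 13438 genes. Symbols were compared with the current rat gene names by gene identifier, which matched 18983 probe sets and changed 0 symbols.

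A single linear model with 1 mean for each of the 10 groups was fitted to each gene with limma 3.58.1 in R 4.3.3, and the variances were moderated with eBayes. Contrasts compared each concentration with the controls of the same time, the change at 4 weeks with the change at 1 week for each concentration, and the 4-week with the 1-week controls. All limma tests were two-sided. P values were adjusted by Benjamini-Hochberg over the 13438 genes within a contrast, and a gene was called at an adjusted p under 0.05. Changes are log2 differences with the standard error of the model. Contrasts of 0.60 with 0.15 mg/m3 and of 4 with 1 week at 0.60 mg/m3 were added after the data had been seen.

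Gene lists for 53 cell types, pathways and responses held 899 symbols, of which 749 were measured. Each list was tested with camera in limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. The same test with an estimated correlation and fry were run beside it. Members called were counted over all genes tested and adjusted over the list alone. Which lists to describe with named members was decided after their values had been seen.

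Response scores measured whether genes that changed at one exposure time also moved at the other. A score was the mean log2 value per array of the genes called at 0.60 mg/m3 at the other time, rising and falling genes apart. Each concentration was compared with the controls of its time by an exact two-sided permutation test of 5 against 5 arrays, whose smallest p is 0.00794, with adjustment over 16 tests. Overlaps of called genes were set against the product of the counts over the number of genes. Where 2 groups shared their controls, overlaps were also set against 20 simulations of unchanged groups and against a split of the controls between the groups.

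Named genes followed a rule that left out symbols starting with LOC or RGD. At 0.60 mg/m3 it took the 10 largest rises and 10 largest falls among called genes whose 5 exposed arrays all lay on one side of the 5 controls. Chance places all arrays of a gene on one side in 0.794% of genes. The same rule took 5 and 5 genes at 0.15 mg/m3, 3 and 3 at 0.08 and 0.04 mg/m3, and 5 and 5 for the controls between times. It took 5 and 5 genes for the difference between times at 0.60 mg/m3 without the condition on sides, and up to 4 called members of each list described. Groups, contrasts, lists, the naming rule and a first set of alternative settings were fixed before the data were examined.

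The alternative settings of that first set were array weights, exclusion of the dimmest 25% of genes, centring of arrays on their median, quantile normalization, and an intensity trend in eBayes. They also included the use of all probe sets or their mean, a replicate block, a model of the compared arrays alone, a minimum change of 1.5-fold, and the omission of each array in turn. Alternatives added after the data had been seen were the position of each array on an axis of spread within the 1-week control and 0.04 mg/m3 arrays as a covariate, and the 4-week controls in place of the 1-week controls. A model of the 25 arrays of 4 weeks, the scores of 3 tissue lists as covariates, and 6 tissue lists at 0.08 mg/m3 at 4 weeks without single arrays were added in the same way. The model was tested on simulated data in which 50 genes were changed at each of 4 sizes. At 1.5-fold it called 80% of the changed genes at 1 week and 96% at 4 weeks, and at 3-fold 100% at both times. It also called 12 and 13 of the unchanged genes. The simulation gave each gene the same independent spread in every group, so the values at the 2 times differ only by the draw. It held no spread shared between genes, so it does not measure false calls where such spread is present. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.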

Results

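Expression of 13438 genes was measured in lung tissue around the distal airways and alveoli of rats that had inhaled nickel subsulfide, a poorly soluble nickel compound that causes lung tumours in rats. The aerosol held 0.60, 0.15, 0.08 or 0.04 mg/m3, which correspond to 0.44, 0.11, 0.06 or 0.03 mg of nickel per m3. Exposure lasted 1 week (5 exposure days) or 4 weeks (20 exposure days), and unexposed controls were taken at each time. Each of the 10 groups had 5 arrays, so n = 5 throughout. The design asks which genes respond, from which concentration, and how the response differs between the exposure times. Values are log2 intensities, changes are log2 differences ± the standard error, and adjusted p values come from limma.

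The 1-week controls and the 1-week 0.04 mg/m3 arrays lay furthest from the 4-week groups. The first principal component of the arrays held 63.5% of the variance and the second 10.5%. Mean positions on the first were -58.0 ± 12.2 (SD, n = 5) for the 1-week controls and -76.5 ± 9.73 for 0.04 mg/m3 at 1 week. The 4-week controls lay at 31.3 ± 3.03 and the 1-week 0.60 mg/m3 arrays at 2.52 ± 3.71. The 1-week 0.08 mg/m3 arrays spread widely (-27.1 ± 26.5, from -64.7 to 5.46), and replicate 1 lay among the 1-week controls. Correlations within a group were at least 0.956.

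**Figure D1:**
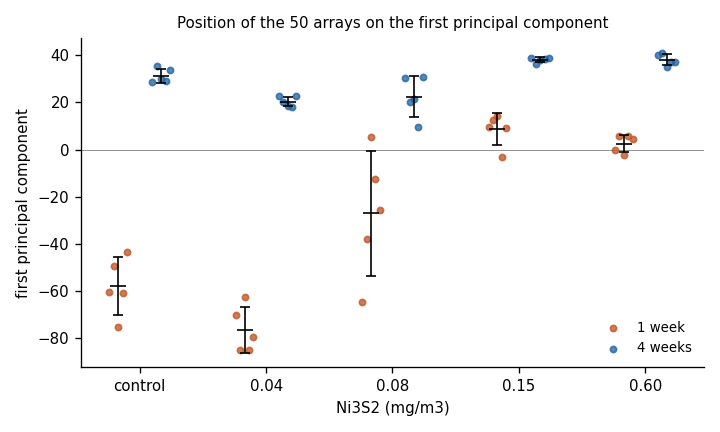
Position of each array on the first principal component (arbitrary units) by group, with 5 arrays per group as points and the mean ± SD in black. The 1-week control arrays lie around -58.0 and the 4-week control arrays around 31.3, with the 1-week groups at 0.15 and 0.60 mg/m3 between them.

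After 4 weeks at 0.60 mg/m3 the largest rise was in Spp1, which encodes osteopontin. It rose 23.5-fold (4.56 ± 0.30, adjusted p = 1.89e-15), from 5.05 ± 0.27 (SD) in controls to 9.60 ± 0.31. The acute-phase gene Saa3 rose 22.5-fold (4.49 ± 0.30). Mmp12, the macrophage elastase, rose 14.6-fold (3.87 ± 0.27), and the anion exchanger gene Slc26a4 rose 15.3-fold (3.94 ± 0.24). Ptges, which makes prostaglandin E2, rose 11.3-fold (3.49 ± 0.23), and Retnla, a marker of alternatively activated macrophages, rose 10.6-fold (3.41 ± 0.27). The 10 largest rises also held the myeloid receptor gene Lilrb4 (3.17 ± 0.23), the monocyte chemokine genes Ccl2 (3.0 ± 0.23) and Ccl7 (2.93 ± 0.27), and Lcn2, a siderophore-binding protein (3.0 ± 0.25). The 10 largest falls were in Acot1, an acyl-CoA thioesterase (-2.85 ± 0.28, 7.21-fold), the glutathione transferase Gsta3 (-2.73 ± 0.18, 6.62-fold), and the actin-severing protein gene Scin (-2.65 ± 0.24). They went on with the zinc transporter Slc39a2 (-2.40 ± 0.19), Serpinb10 (-2.36 ± 0.25), the ribonuclease gene Rnase3 (-2.36 ± 0.20), the phospholipase Pla2g2d (-2.09 ± 0.20), the uroplakin gene Upk1a (-2.07 ± 0.21), the cytochrome P450 gene Cyp2a3 (-1.97 ± 0.18) and Azgp1 (-1.78 ± 0.14). In all, 2334 genes were called, 1273 higher and 1061 lower, and 740 of them changed at least 1.5-fold. With arrays centred on their median, 37.1% of the called genes were higher in place of 54.5%.

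Interferon-induced genes rose together at 4 weeks of 0.60 mg/m3. Of 23 members 20 rose and 0 fell (21 adjusted over the list alone), with a median change of 0.72 (adjusted p = 1.61e-22, and adjusted p = 0.0085 with an estimated correlation). The largest rises were in the T cell attractant Cxcl10 (2.75 ± 0.29), in Ifit3 (2.27 ± 0.32), Mx1 (2.24 ± 0.27) and Usp18 (2.10 ± 0.21). The T cell attractant Cxcl11, a member of the chemokine list only, rose by 2.43 ± 0.31. Chemokine genes rose as a list, with 13 of 26 higher and 2 lower (16 adjusted over the list alone, adjusted p = 6.98e-08, and adjusted p = 0.0304 with an estimated correlation). Cytokines and innate signals had 6 of 17 higher and 1 lower (9 adjusted over the list alone, adjusted p = 0.00046, and adjusted p = 0.00729 with an estimated correlation). Among them were Ptgs2, which starts prostaglandin synthesis (1.79 ± 0.25), Tnf (1.06 ± 0.17) and the interleukin 1 antagonist Il1rn (0.73 ± 0.13). Acute-phase and secreted defence genes had 9 of 19 higher and 1 lower (10 adjusted over the list alone, adjusted p = 2.85e-08, and adjusted p = 0.00148 with an estimated correlation), with the chitinase-like Chi3l1 at 1.20 and the chitinase Chia at 1.00. Complement genes had 11 of 16 higher and 0 lower (12 adjusted over the list alone, adjusted p = 4.02e-11, and adjusted p = 0.000465 with an estimated correlation), including Cfi (1.17), C6 (1.15), C2 (0.97) and C1qb (0.89).

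Genes of dividing cells, sterol synthesis, stress and glucose use also rose at 0.60 mg/m3 after 4 weeks. Of 34 genes of G2/M and mitosis 26 were higher and 1 lower (31 adjusted over the list alone), with a median change of 0.86, including Melk (1.66 ± 0.27), Top2a (1.64 ± 0.22) and Mki67 (1.53 ± 0.25). Their adjusted p was 2.25e-16, but adjusted p = 0.0747 with an estimated correlation. Of 27 genes of G1/S and DNA replication 13 were higher and 0 lower (16 adjusted over the list alone, adjusted p = 5.75e-07, but adjusted p = 0.198 with an estimated correlation). They included the ribonucleotide reductase subunit Rrm2 (1.24 ± 0.22) and Ccne2 (1.10). Cholesterol synthesis genes had 14 of 17 higher and 0 lower (14 adjusted over the list alone, median 0.51, adjusted p = 1.01e-13, and adjusted p = 0.00148 with an estimated correlation). Cyp51 was at 1.21 ± 0.11 and Idi1 at 1.18 ± 0.18. The unfolded protein and integrated stress response had 14 of 24 higher and 0 lower (17 adjusted over the list alone, median 0.32, adjusted p = 3.55e-12, and adjusted p = 0.000465 with an estimated correlation). The stress regulators Ddit3, Trib3 and Atf3 were at 1.10, 1.04 and 1.02. Hypoxia targets had 11 of 22 higher and 1 lower (13 adjusted over the list alone, adjusted p = 4.65e-06, and adjusted p = 0.00466 with an estimated correlation). The prolyl hydroxylase Egln3 rose by 2.15 ± 0.24 and P4ha1 by 0.99. Glycolysis genes had 9 of 14 higher and 0 lower (10 adjusted over the list alone, adjusted p = 6.98e-08, and adjusted p = 0.0085 with an estimated correlation). The lactate exporter Slc16a3 rose by 2.36 ± 0.18 and Ldha by 0.60.

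Club cell genes and genes of foreign-compound metabolism fell at 0.60 mg/m3 after 4 weeks. Xenobiotic metabolism had 13 of 20 members lower and 0 higher (14 adjusted over the list alone), with a median of -0.56 (adjusted p = 5.28e-14, and adjusted p = 0.00133 with an estimated correlation). Club cell genes had 6 of 10 lower and 0 higher (6 adjusted over the list alone, adjusted p = 2.6e-09, and adjusted p = 0.0085 with an estimated correlation). The cytochrome P450 genes Cyp2f4 (-1.25 ± 0.11) and Cyp4b1 (-0.88 ± 0.08) and Gsta3 belong to both lists, and Gstm2 changed by -1.14. Goblet cell genes had 5 of 12 higher and 0 lower (5 adjusted over the list alone, adjusted p = 0.0149), with the gel-forming mucin Muc5b at 1.93 ± 0.29 and Bpifb1 at 0.96, and adjusted p = 0.288 with an estimated correlation. NRF2 targets, the genes of the oxidant response, moved both ways, with 3 of 20 higher and 5 lower (10 adjusted over the list alone, adjusted p = 0.159). Slc7a11 (1.41) and haem oxygenase Hmox1 (1.39 ± 0.12) rose, and the quinone reductase Nqo1 fell (-1.09 ± 0.08). Of 15 genes of metal binding and transport 4 were higher and 1 lower (5 adjusted over the list alone, adjusted p = 0.068), with metallothionein Mt2A at 1.28 ± 0.17, Slc39a8 at 0.84 and Mt3 at -0.77.

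Marker genes of immune cells differed in direction at 0.60 mg/m3 after 4 weeks. MHC class II genes had 8 of 10 higher and 0 lower (8 adjusted over the list alone, adjusted p = 1.78e-06), with Cd86 at 1.11 and RT1-DMa at 0.72, and adjusted p = 0.0789 with an estimated correlation. T cell genes had 8 of 16 higher and 0 lower (12 adjusted over the list alone, adjusted p = 4.65e-06), with Icos at 1.16 and Cd3e at 0.95, and adjusted p = 0.198 with an estimated correlation. T cell genes did not follow the concentration at 4 weeks. The mean log2 value of the list relative to all arrays was -0.414 in controls. It was 0.328, 0.006, -0.209 and 0.135 from the lowest to the highest concentration. Plasma cell genes had 3 of 6 higher, with Jchain, which joins antibody chains, at 1.61 ± 0.24 (3 adjusted over the list alone, adjusted p = 0.00334, and adjusted p = 0.0789 with an estimated correlation). NK and cytotoxic cell genes had 7 of 12 lower and 2 higher (10 adjusted over the list alone, adjusted p = 0.0123), with the granzymes Gzmb at -1.05 and Gzma at -0.99, and adjusted p = 0.332 with an estimated correlation. Neutrophil genes had 5 of 10 higher and 1 lower (7 adjusted over the list alone, adjusted p = 0.00354), with Il1r2 at 1.51, S100a9 at 1.05 and Cxcr1 at -1.39, and adjusted p = 0.224 with an estimated correlation. The rise of S100a8 (0.86) was lost without replicate 5 of the exposed arrays (0.75, adjusted p = 0.0589). Alveolar macrophage genes had 4 of 14 higher and 3 lower (9 adjusted over the list alone), with a median of -0.14, a mean of 0.24 and a test direction upwards (adjusted p = 0.525). Alveolar type 2 cell genes had 7 of 13 higher and 2 lower (9 adjusted over the list alone, adjusted p = 0.0127), with Fabp5 at 1.03, Napsa at 0.53 and Etv5 at -0.65, and adjusted p = 0.359 with an estimated correlation.

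Of 28 extracellular matrix and remodelling genes 7 were higher and 0 lower after 4 weeks at 0.60 mg/m3 (8 adjusted over the list alone), and the matrix protease Mmp7 (1.93 ± 0.15) and fibronectin Fn1 (0.61) were among them. The list's adjusted p was 0.00149, and adjusted p = 0.332 with an estimated correlation. Lysosome and lipid handling genes had 9 of 20 higher and 0 lower (11 adjusted over the list alone, adjusted p = 0.000204), with Gpnmb at 1.20, Ctsz at 0.72 and Apoe at 0.60, and adjusted p = 0.116 with an estimated correlation. Endothelial genes had 4 of 11 lower and 0 higher (4 adjusted over the list alone, adjusted p = 0.00222), with the junction protein Cldn5 at -0.48 and Plvap at -0.45, and adjusted p = 0.358 with an estimated correlation.

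**Figure D2:**
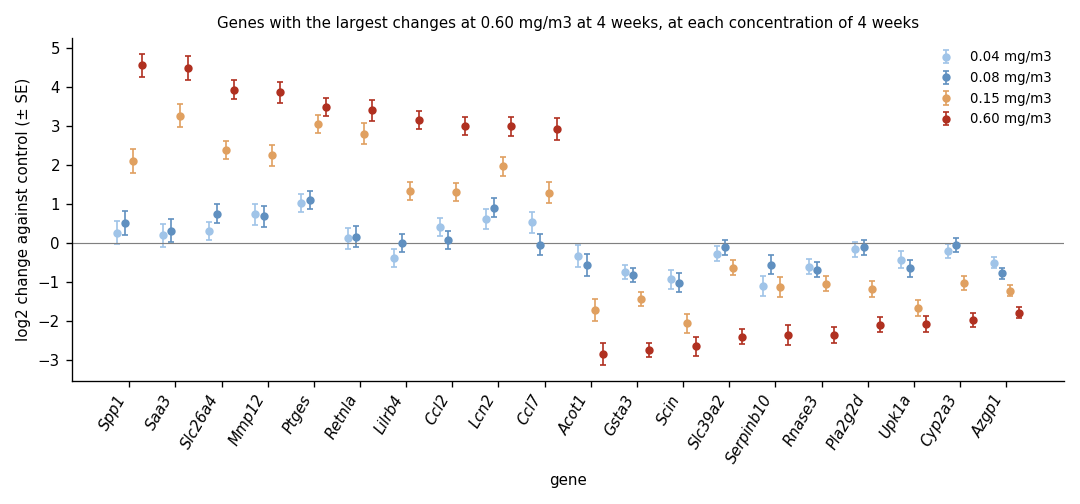
Log2 change against the 4-week controls (points, with the standard error as bars) at 4 concentrations for the 20 genes with the largest rises and falls at 0.60 mg/m3, with 5 arrays per group. Spp1 rises from 2.11 at 0.15 mg/m3 to 4.56 at 0.60 mg/m3, and Gsta3 falls from -1.43 to -2.73.

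At 0.15 mg/m3 for 4 weeks Tdh, the threonine dehydrogenase gene, rose most (3.57 ± 0.21, 11.9-fold), followed by Saa3 (3.27 ± 0.30, 9.64-fold), Ptges (3.05 ± 0.23), Retnla (2.81 ± 0.27) and Slc26a4 (2.39 ± 0.24). The largest falls were in Scin (-2.06 ± 0.24, 4.17-fold), Acot1 (-1.71 ± 0.28), Upk1a (-1.66 ± 0.21), Gsta3 (-1.43 ± 0.18) and Azgp1 (-1.22 ± 0.14). The test called 470 genes, 258 higher and 212 lower, of which 200 changed at least 1.5-fold. Mitosis genes had 22 of 34 higher and 0 lower (26 adjusted over the list alone, median 0.81, adjusted p = 2.68e-32, and adjusted p = 0.00798 with an estimated correlation). Cholesterol synthesis had 10 of 17 higher (14 adjusted over the list alone), and the unfolded protein and integrated stress response 8 of 24 (14 adjusted over the list alone). Acute-phase genes had 7 of 19 higher (8 adjusted over the list alone) and complement 4 of 16 (6 adjusted over the list alone), and 0 members of these 4 lists were lower. With an estimated correlation adjusted p was 0.000129 for each but complement, which had adjusted p = 0.00102. Xenobiotic metabolism had 7 of 20 lower and 0 higher (9 adjusted over the list alone, adjusted p = 0.00997 with an estimated correlation). Interferon genes had 3 of 23 higher (8 adjusted over the list alone, adjusted p = 7.36e-09), but adjusted p = 0.156 with an estimated correlation.

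Of the genes called at both 0.15 and 0.60 mg/m3 at 4 weeks, 238 were higher at both, 194 were lower at both and 0 moved in opposite directions. Independent calls would share 24 higher and 17 lower. The concentrations share their controls, and the correlation of changes across genes was 0.82 (covariance 0.055) against 0.48 (covariance 0.0055) in simulations of unchanged groups. With different control arrays for each concentration, 79 higher and 36 lower genes were shared and the correlation was 0.73 (covariance 0.0519). Genes are not independent replicates. Between 0.15 and 0.60 mg/m3, 385 genes differed, 257 higher and 128 lower at 0.60 mg/m3.

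After 4 weeks, muscle creatine kinase Ckm rose 7.07-fold at 0.08 mg/m3 (2.82 ± 0.56, adjusted p = 0.000934) and 5.88-fold at 0.04 mg/m3 (2.56 ± 0.56). Skeletal muscle genes lay apart in replicate 1 of 0.08 mg/m3, where Ckm was at 11.90 against a mean of 7.11 in the other arrays. Without that array the rise of Ckm was 1.86 ± 0.41 (adjusted p = 0.00241). Glycam1, a ligand of lymphocyte homing receptors, rose 5.18-fold (2.37 ± 0.64) and 8.59-fold (3.10 ± 0.64). Hjv, a gene of muscle and liver, rose at 0.08 mg/m3 (2.48 ± 0.43, and 1.96 ± 0.40 without replicate 1, adjusted p = 0.00113). The lymphoid chemokine gene Ccl19 rose at 0.04 mg/m3 (2.51 ± 0.34). Falls at 0.08 mg/m3 were led by the replication inhibitor geminin, Gmnn (-0.94 ± 0.15), Ccdc68 (-0.90 ± 0.25) and C8h11orf65 (-0.87 ± 0.16), and at 0.04 mg/m3 by Serpinb10 (-1.10 ± 0.25), Akap5 (-0.99 ± 0.32) and Slc6a14 (-0.93 ± 0.23). Ckm at 0.08 mg/m3 had an adjusted p of 0.0839 when only the compared arrays were modelled. Ccdc68 was lost without replicate 4 of 0.08 mg/m3 (-0.80, adjusted p = 0.0719), and Akap5 without any of several arrays (-0.89, adjusted p = 0.0938 without control replicate 5).

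Heart muscle genes, which in rats are also expressed in the walls of pulmonary veins, had 13 of 13 higher at 0.04 mg/m3 (13 adjusted over the list alone, median 1.91, adjusted p = 3.8e-14). At 0.08 mg/m3 7 of 13 were higher (13 adjusted over the list alone, median 1.31, adjusted p = 2.73e-08). At 0.15 and 0.60 mg/m3 their medians were 0.27 and -0.05, and 0 members were called by limma. Smooth muscle genes had 11 of 14 higher at both low concentrations (12 adjusted over the list alone at each, medians 0.86 and 0.73). B cell genes had 7 of 8 higher at 0.04 mg/m3 (7 adjusted over the list alone, median 1.24) and 6 of 8 at 0.08 mg/m3 (7 adjusted over the list alone, median 0.92). T cell genes had 12 of 16 higher (12 adjusted over the list alone) and 3 of 16 (10 adjusted over the list alone). Counts at 0.08 mg/m3 depended on single arrays. Without exposed replicate 2 or 4, 1 B cell and 0 T cell genes were called, and without replicate 1, 8 T cell genes. Heart muscle had 4 called members without replicate 2 or 3 and 9 without replicate 1 or 5. With an estimated correlation none of these held. At 0.04 mg/m3 heart muscle had adjusted p = 0.175, smooth muscle 0.105 and B and T cells 0.27, each with an estimated correlation. At 0.08 mg/m3 it was adjusted p = 0.274 for heart muscle, 0.0523 for smooth muscle, 0.321 for B cells and 0.331 for T cells, each with an estimated correlation. Skeletal muscle and adipocyte genes had 2 of 10 and 3 of 10 members higher at 0.08 mg/m3 (8 and 7 adjusted over the list alone), with adjusted p = 0.321 for each list with an estimated correlation. The skeletal muscle score was 6.11 in replicate 1 against a mean of -0.01 in the other arrays. Without that array 1 member was higher, and the list did not pass (median 0.23 in place of 1.69, adjusted p = 0.186). Adipocyte scores were 1.92 and 1.69 in replicates 1 and 3 and at most 0.02 in the other 3 arrays.

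The counts were 1734 genes at 0.04 mg/m3, 1114 higher and 620 lower, and 1147 at 0.08 mg/m3, 762 higher and 385 lower. They shared 579 higher and 256 lower genes, where independent calls would share 63 and 18. The correlation was 0.85 (covariance 0.0666) against 0.64 (covariance 0.0109) in simulations with shared controls, and 0.75 (covariance 0.0609) with different control arrays, when 136 higher and 17 lower genes were shared. The simulations for 0.15 and 0.60 mg/m3 drew on the same controls and residuals, so their 0.48 (covariance 0.0055) differs from this 0.64 only by the draw. With the heart muscle, smooth muscle and B cell scores of each array as covariates, 1 gene was called at 0.04 mg/m3 and 6 at 0.08 mg/m3, against 512 at 0.15 and 1898 at 0.60 mg/m3. Among genes called without the covariates the median size of the change went from 0.43 to 0.16 at 0.04 mg/m3 and from 0.47 to 0.25 at 0.08 mg/m3, and the median standard error from 0.12 to 0.18 and 0.16. At 0.08 mg/m3 Ccdc68 (-0.82 ± 0.37), Gmnn (-0.73 ± 0.20) and C8h11orf65 (-0.60 ± 0.22) lost their calls but kept most of their change. Hjv (1.25 ± 0.46) and Glycam1 (0.68 ± 0.64) became smaller there, as did Glycam1 (0.57 ± 0.75), Ccl19 (0.76 ± 0.33), Akap5 (-0.20 ± 0.51) and Slc6a14 (-0.23 ± 0.38) at 0.04 mg/m3. The scores separate these groups from the controls, so the loss of calls does not show that the changes went away. Centring arrays on their median left 39.6% of called genes higher at 0.04 mg/m3 in place of 64.2%, and 36.5% at 0.08 mg/m3 in place of 66.4%. At 0.04 mg/m3, 948 genes were called without control replicate 2, 971 without exposed replicate 3 and 991 without exposed replicate 4, and at 0.08 mg/m3 606 without exposed replicate 4 and 683 without control replicate 2.

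After 1 week at 0.60 mg/m3, Retnla rose 25.5-fold (4.67 ± 0.27, adjusted p = 4.18e-18), from 8.36 ± 0.17 (SD) to 13.03 ± 0.09, and Saa3 rose 23.1-fold (4.53 ± 0.30). Genes of dividing cells followed, with Rrm2 at 3.83 ± 0.22 (14.2-fold), the kinase gene Melk at 3.66 ± 0.27 (12.7-fold), and Cdkn3 at 3.47 ± 0.24. The mitotic motor Kif20a was at 3.43 ± 0.21 and the cyclins Ccna2 at 3.30 ± 0.23 and Ccnb2 at 3.26 ± 0.19. The proton pump subunit Atp6v0a4 (3.33 ± 0.32) and Spp1 (3.33 ± 0.30) completed the 10 largest rises. In the 1-week controls Saa3 (3.55), Melk (3.72) and Atp6v0a4 (3.52) lay near the 25th percentile of the arrays (3.56), where changes are compressed. Against the 4-week controls their changes were smaller, at 3.87, 2.97 and 3.26. Their folds at 1 week thus depend on the control group and are not lower bounds. The 10 largest falls were in Upk1a (-2.57 ± 0.21, 5.94-fold), Slc27a3 (-2.20 ± 0.18), the glycine methyltransferase gene Gnmt (-2.15 ± 0.22), Zfp654 (-2.13 ± 0.19) and the stress cytokine gene Gdf15 (-2.07 ± 0.22). They went on with the clock gene Per1 (-2.06 ± 0.18), the retinol receptor gene Stra6 (-2.02 ± 0.29), Zbtb41 (-1.87 ± 0.28), Depp1 (-1.86 ± 0.22) and Dact3 (-1.80 ± 0.16). Against the 4-week controls all 10 rises held, from 2.21 for Cdkn3 to 3.87 for Saa3. Of the falls, Upk1a (-1.08), Zfp654 (-1.22), Per1 (-0.69) and Zbtb41 (-1.87) were also called against the 4-week controls, Slc27a3 (-0.36), Gnmt (-0.48) and Depp1 (-0.47) were not, and Gdf15 (0.17), Stra6 (1.00) and Dact3 (0.31) had the opposite sign.

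The test called 8742 genes at 0.60 mg/m3 after 1 week, 4408 higher and 4334 lower, of which 5136 changed at least 1.5-fold. Of the 8742 called genes, 1836 (21%) were also called in the same direction against the 4-week controls, 1336 higher and 500 lower. Another 3148 were called in the opposite direction. Against the 4-week controls 6637 genes were called in all, 4469 higher and 2168 lower. Both comparisons use the same exposed arrays. No number for independent calls was computed, so the 1836 shared calls alone support no call. The correlation of the changes against the 1-week and the 4-week controls was 0.03 across genes. On the leading axis of spread within the 1-week control and 0.04 mg/m3 arrays, the 1-week controls lay at 42.9 ± 16.2 (SD), the 4-week controls at -26.4 ± 1.7 and the 1-week 0.60 mg/m3 arrays at 1.7 ± 5.5.

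Cell division genes rose at 1 week of 0.60 mg/m3 against both control groups. Of 34 mitosis genes 30 were higher and 0 lower than in the 1-week controls (30 adjusted over the list alone, median 1.56, adjusted p = 8.41e-11), and 26 were higher against both, although adjusted p = 0.573 with an estimated correlation. Of 27 genes of G1/S and DNA replication 25 were higher and 0 lower (25 adjusted over the list alone, median 1.16, adjusted p = 3.96e-09, and adjusted p = 0.573 with an estimated correlation). Of these, 24 were higher against both, among them Mcm6 (2.43 ± 0.16, and 1.64 against the 4-week controls) and Uhrf1 (1.81 and 2.06). Cholesterol synthesis had 12 of 17 higher and 3 lower (15 adjusted over the list alone, adjusted p = 0.00538, and adjusted p = 0.573 with an estimated correlation), with 9 members higher against both. Sqle was at 1.75 ± 0.15 (0.69 against the 4-week controls) and Cyp51 at 1.74 ± 0.11 (1.09). The unfolded protein and integrated stress response had 17 of 24 higher and 3 lower (21 adjusted over the list alone, adjusted p = 0.00306, and adjusted p = 0.573 with an estimated correlation), with 12 members higher against both. The serine synthesis gene Psat1 was at 1.94 ± 0.13 (0.90 against the 4-week controls) and the asparagine synthetase Asns at 1.49 (0.90).

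Secretory and defence genes moved member by member at 1 week of 0.60 mg/m3, and their lists did not pass the test against the 1-week controls. Against the 4-week controls the goblet cell (adjusted p = 0.0115), acute-phase (adjusted p = 0.014) and complement (adjusted p = 0.0111) lists passed upwards. With an estimated correlation they had adjusted p = 0.435, 0.245 and 0.245. Goblet cell genes had 6 of 12 higher and 1 lower (7 adjusted over the list alone, adjusted p = 0.541), with Muc5b at 1.83 ± 0.29 (2.23 against the 4-week controls) and 5 members higher against both. Acute-phase genes had 11 of 19 higher and 1 lower (12 adjusted over the list alone, adjusted p = 0.115), with Lcn2 at 1.39 (1.33) and Chi3l1 at 1.16 (1.54), and 8 higher against both. Complement genes had 7 of 16 higher and 6 lower (13 adjusted over the list alone, adjusted p = 0.783), with Cfi at 2.62 ± 0.21 (1.21) and Cfd at -1.19 (0.30), and 5 higher against both. Metal binding and transport genes had 9 of 15 higher and 2 lower (11 adjusted over the list alone, adjusted p = 0.36), with Mt2A at 1.84 ± 0.17 (1.98) and the zinc importer Slc39a8 at 1.15 (-0.49), and 6 higher against both. Matrix and remodelling genes had 10 of 28 higher and 11 lower (21 adjusted over the list alone), with a median of 0.04, a mean of 0.11 and a test direction downwards (adjusted p = 0.883). The protease inhibitor Timp1 (2.48 ± 0.16, and 1.96) and Mmp12 (1.97 ± 0.27, and 1.47) rose against both controls, as did 4 of the 28 members in all. Another 8 were called against both in opposite directions. Neutrophil genes had 5 of 10 higher and 2 lower (8 adjusted over the list alone, adjusted p = 0.456), with Il1r2 at 1.82 (1.36), Cxcr1 at 1.65 (0.01), S100a8 at 1.34 (0.07) and S100a9 at 0.66 (0.08), and 1 higher against both.

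The direction of several smooth muscle and immediate early genes at 1 week of 0.60 mg/m3 depended on the control group. Smooth muscle genes had 11 of 14 lower and 1 higher at 0.60 mg/m3 (12 adjusted over the list alone, median -1.12, adjusted p = 0.00594, and adjusted p = 0.745 with an estimated correlation). Of the members, 7 were called against both control groups with opposite signs. The intermediate filament gene Des was at -1.57 ± 0.23 against the 1-week and 1.38 against the 4-week controls, and Acta2 at -1.48 and 0.56. Immediate early genes had 12 of 17 lower and 2 higher (15 adjusted over the list alone, median -0.57, adjusted p = 0.00538, and adjusted p = 0.573 with an estimated correlation). Of the 17, 3 were called lower against both controls and 6 were called against both with opposite signs. Zfp36, which destabilises cytokine messengers, was lower against both (-1.53 ± 0.12 and -0.53). Heart muscle genes had 10 of 13 higher and 0 lower (10 adjusted over the list alone, adjusted p = 0.253), with Tnnc1 at 2.28 ± 0.45 against the 1-week and 0.32 against the 4-week controls.

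**Figure D3:**
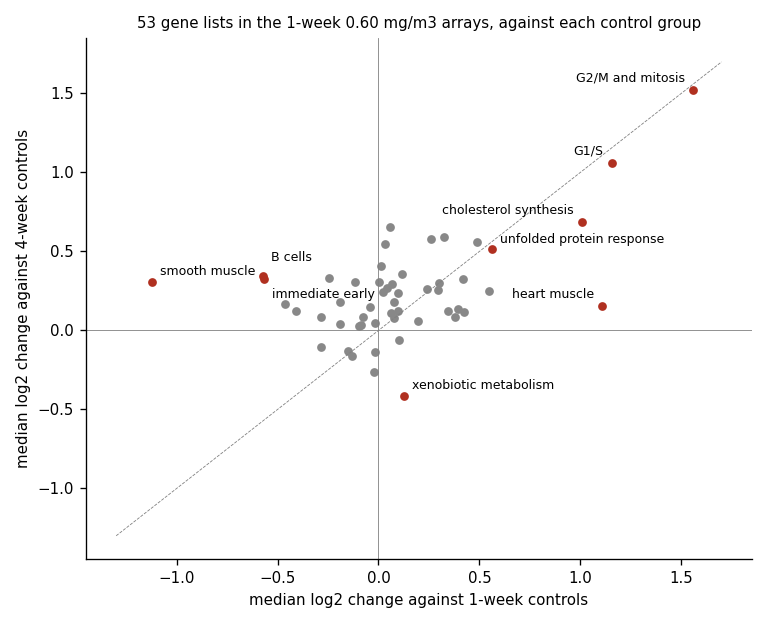
Median log2 change of each of 53 gene lists in the 1-week 0.60 mg/m3 arrays against the 1-week controls (horizontal axis) and against the 4-week controls (vertical axis), 5 arrays per group. Mitosis genes lie at 1.56 and 1.52, and smooth muscle genes, at -1.12 against the 1-week controls, lie above 0 against the 4-week controls.

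At 0.15 mg/m3 for 1 week the largest rises were again in Retnla (4.07 ± 0.27, 16.8-fold), Saa3 (3.69 ± 0.30, 12.9-fold), Rrm2 (3.23 ± 0.22), Melk (3.16 ± 0.27) and Cdkn3 (3.04 ± 0.24). Against the 4-week controls they were 3.21, 3.03, 1.88, 2.47 and 1.77. The largest falls were in Upk1a (-2.60 ± 0.21), Gdf15 (-2.39 ± 0.22), Stra6 (-2.29 ± 0.29), Zfp654 (-2.20 ± 0.19) and Des (-2.15 ± 0.23). Against the 4-week controls these were -1.10, -0.15, 0.73, -1.29 and 0.80. Mitosis genes had 29 of 34 higher and 0 lower (29 adjusted over the list alone, adjusted p = 2.8e-07, and adjusted p = 0.922 with an estimated correlation). Replicate 1 had a mitosis score of -0.184 against 0.596 to 1.11 in the other arrays of the group and at most -0.595 in the 1-week controls. Retnla, Rrm2, Melk and Cdkn3 were also lowest in that array of the group. The test called 9063 genes, 4536 higher and 4527 lower. Of these, 1634 (18%) were called in the same direction and 2681 in the opposite direction against the 4-week controls. There, 5729 genes were called in all, 3903 higher and 1826 lower. No number for independent calls was computed for the 2 control groups, so the 1634 shared calls alone support no call. The 0.15 and 0.60 mg/m3 groups shared 4186 higher and 4062 lower genes, where independent calls would share 1488 and 1460. The correlation was 0.98 (covariance 0.448). Simulations with shared controls gave 0.51 (covariance 0.00894), and different control arrays 0.97 (covariance 0.443). Between 0.60 and 0.15 mg/m3 at 1 week 2 genes differed, 1 in each direction.

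At 0.08 mg/m3 for 1 week Tdh (1.64 ± 0.21, 3.11-fold), Rrm2 (1.63 ± 0.22, 3.09-fold) and the glycogen regulator Ppp1r3b (1.59 ± 0.17, 3.0-fold) rose most. Zfp654 (-1.46 ± 0.19), Upk1a (-1.42 ± 0.21) and the transcription factor gene Cebpd (-1.35 ± 0.15) fell most. Against the 4-week controls Tdh was at 1.55, Rrm2 at 0.28, Ppp1r3b at -0.50, Zfp654 at -0.54, Upk1a at 0.08 and Cebpd at -0.26. Immediate early genes had 14 of 17 lower and 0 higher (14 adjusted over the list alone, adjusted p = 4.36e-07, and adjusted p = 0.15 with an estimated correlation). Mitosis genes had 18 of 34 higher (18 adjusted over the list alone, adjusted p = 0.00139, and adjusted p = 0.994 with an estimated correlation). Neither list passed against the 4-week controls. There, immediate early genes had 2 of 17 lower and 6 higher (median 0.10, adjusted p = 0.861) and mitosis genes 8 of 34 higher and 6 lower (median 0.07, adjusted p = 0.861). The test called 6537 genes, 3374 higher and 3163 lower. Of these, 870 (13.3%) had the same and 4099 the opposite direction against the 4-week controls. No number for independent calls was computed, so the 870 shared calls alone support no call.

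At 0.04 mg/m3 for 1 week changes were smaller, and the arrays lay on the side of the 1-week controls. The transglutaminase gene Tgm1 (1.05 ± 0.34), Nell1 (0.91 ± 0.20) and Tent5b (0.88 ± 0.21) rose most, and the complement receptor gene Cr2 of B cells (-1.29 ± 0.30), the fatty acid desaturase gene Scd (-1.28 ± 0.39) and Zeb2 (-1.23 ± 0.24) fell most. Smooth muscle genes had 8 of 14 lower and 0 higher (9 adjusted over the list alone, adjusted p = 1.77e-05). B cell genes had 7 of 8 lower (7 adjusted over the list alone, adjusted p = 0.000196). Each list had adjusted p = 0.989 with an estimated correlation. Neither list passed against the 4-week controls, with 11 of 14 smooth muscle genes higher and 3 lower (median 1.04, adjusted p = 0.929) and 3 of 8 B cell genes higher and 3 lower (median -0.07, adjusted p = 0.987). The test called 3614 genes, 2035 higher and 1579 lower, and 385 changed at least 1.5-fold. Of the called genes, 3151 (87.2%) were called in the same and 138 in the opposite direction against the 4-week controls, at a correlation of 0.64 across genes. Both comparisons use the same exposed arrays and no value for unchanged groups was computed, so this agreement supports no call. On the axis of spread described above the exposed arrays lay at 50.3 ± 13.1 (SD), from 31.02 to 64.82. The 1-week controls lay at 42.9 ± 16.2, from 22.54 to 63.5, so the ranges overlapped, and the axis was defined on these arrays. Of the 6 named genes Cr2 lost its call against the 4-week controls (-0.55, adjusted p = 0.0851). With arrays centred on their median, which moved the median change of all genes by 0.11, 81.7% of called genes were higher in place of 56.3%. Without exposed replicate 4 or 5 the counts were 2261 and 2327, and without replicate 5 Tgm1 was lost (0.98, adjusted p = 0.0526). With 0.08 mg/m3 it shared 420 higher and 329 lower genes, and 726 moved in opposite directions, where independent calls would share 511 and 372. The correlation was 0.01 (covariance 0.000729) against 0.46 (covariance 0.00763) in simulations with shared controls, and -0.10 (covariance -0.0117) with different control arrays, when 95 higher and 100 lower genes were shared.

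**Figure D4:**
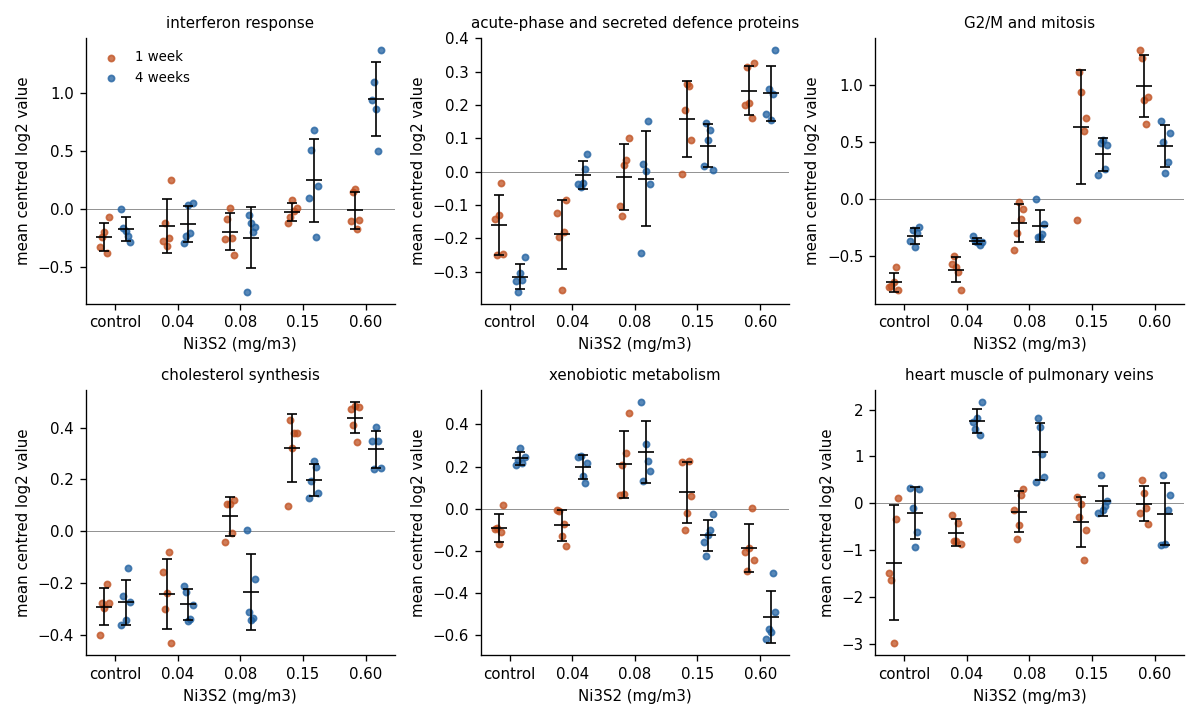
Score of 6 gene lists per array (mean log2 value of the members relative to all arrays) by concentration in mg/m3, for 1 week in orange and 4 weeks in blue, with 5 arrays per group as points and the mean ± SD in black. Interferon scores are highest at 0.60 mg/m3 at 4 weeks, where the median member is 0.72 above the controls, and heart muscle scores at 4 weeks are raised at 0.04 mg/m3, where the median is 1.91.

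The change at 0.60 mg/m3 differed between 4 weeks and 1 week for 7616 genes, 3716 with a higher and 3900 with a lower change at 4 weeks. The 5 largest positive differences were in Ccl19 (3.0 ± 0.48), the interferon regulator Irf7 (2.91 ± 0.31), Ptges (2.72 ± 0.33), the phosphatase gene Dusp2 (2.68 ± 0.32) and Zfp654 (2.65 ± 0.27). The 5 largest negative ones were in Cxcr1 (-3.04 ± 0.34), the histidyl-tRNA synthetase gene Hars1 (-2.83 ± 0.40), Rrm2 (-2.59 ± 0.30), the heart muscle gene Myoz2 (-2.53 ± 0.65) and Gzma (-2.48 ± 0.36). All 10 also differed between the controls, with the opposite sign, from -3.53 for Ccl19 to 2.61 for Hars1. In the exposed arrays alone Zfp654 (1.74 ± 0.19) and Irf7 (1.39 ± 0.22) were higher and Cxcr1 (-1.40 ± 0.24) and Rrm2 (-1.24 ± 0.22) lower at 4 weeks than at 1 week. The other 6 were not called there, with Ccl19 at -0.54, Ptges at 0.19, Dusp2 at 0.44, Hars1 at -0.22, Myoz2 at -0.26 and Gzma at -0.36, so their differences come mostly from the controls. Irf7, Cxcr1 and Rrm2 also differed by more between the controls (-1.53, 1.64 and 1.35) than in the exposed arrays, and Zfp654 by less (-0.91). Interferon genes had 15 of 23 with a higher and 1 with a lower change at 4 weeks (median 0.81, adjusted p = 0.000724). Mitosis genes had 21 of 34 with a lower and 2 with a higher change (median -0.98, adjusted p = 0.000405). Each list had adjusted p = 0.971 with an estimated correlation. In the exposed arrays alone, without either control group, 18 of 23 interferon genes were higher at 4 weeks than at 1 week (adjusted p = 4.8e-10). Of 27 replication genes 25 were lower and 1 higher (adjusted p = 1.06e-07), and each list had adjusted p = 0.978 with an estimated correlation. Of all 7226 genes called in these arrays 5005 were lower, and the median change of all genes was -0.13. The corresponding counts were 1613 genes at 0.04 mg/m3, 5964 at 0.08 mg/m3 and 7629 at 0.15 mg/m3. At 0.04 mg/m3, centring moved the median difference of all genes by -0.15 and the share of positive differences from 60.1 to 21.8%.

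Between the unexposed groups, 9873 genes differed, 4734 higher and 5139 lower at 4 weeks than at 1 week, and 3205 of them changed at least 2-fold. Hars1 (2.61 ± 0.28), the cardiac stress gene Ankrd1 (2.58 ± 0.44), Igsf6 (2.23 ± 0.25), the fibrinogen gene Fgg (2.20 ± 0.21) and Gzma (2.12 ± 0.25) were higher at 4 weeks. Ccl19 (-3.53 ± 0.34, 11.6-fold), Stra6 (-3.02 ± 0.29), Des (-2.95 ± 0.23), the keratin Krt17 (-2.85 ± 0.31) and the lymphocyte gene Ptprcap (-2.71 ± 0.25) were lower. Smooth muscle genes had 11 of 14 lower and 1 higher (median -1.43, adjusted p = 0.0327), and immediate early genes 13 of 17 lower and 0 higher (median -0.76, adjusted p = 0.0318), each with adjusted p = 0.999 with an estimated correlation.

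Genes that rose at 0.60 mg/m3 at 4 weeks also rose at 1 week in groups not used to choose them. Their mean per array was 7.40 ± 0.07 (SD, n = 5) at 0.60 mg/m3 for 1 week against 7.03 ± 0.04 in the 1-week controls. The difference was 0.37 (exact two-sided permutation p = 0.00794, the smallest possible, adjusted p = 0.0141 over 16 tests), and 5 of 5 arrays lay outside the range of the controls. Array counts given below with the scores are of arrays outside that range on either side. At 0.15 mg/m3 the difference was 0.28 in 5 of 5 arrays (exact permutation test, adjusted p = 0.0141), at 0.08 mg/m3 0.08 in 3 of 5 (adjusted p = 0.0684) and at 0.04 mg/m3 -0.02 in 1 of 5 (adjusted p = 0.372). Genes that fell at 4 weeks were lower at 1 week by -0.16 at 0.60 mg/m3 (5 of 5 arrays, adjusted p = 0.0141) and -0.10 at 0.15 mg/m3 (3 of 5, adjusted p = 0.0317). They differed by 0.03 at 0.08 mg/m3 (4 of 5, lying on both sides of the controls, adjusted p = 0.468) and were higher by 0.10 at 0.04 mg/m3 (5 of 5, adjusted p = 0.0141). At 4 weeks, genes that rose at 1 week differed by -0.04, -0.05, 0.06 and 0.07 from the lowest to the highest concentration (5 of 5 arrays and adjusted p = 0.0141 at each). Genes that fell at 1 week differed by 0.13 (5 of 5, adjusted p = 0.0141), 0.10 (4 of 5, adjusted p = 0.0317), -0.06 (4 of 5, adjusted p = 0.0254) and -0.03 (3 of 5, lying on both sides of the controls, adjusted p = 0.209). With 1 array left out, the fall at 0.15 mg/m3 at 1 week had an adjusted p of 0.0741 without control replicate 1, 2 or 5 and 0.0586 without replicate 3. The difference of falling genes at 0.08 mg/m3 at 4 weeks had one of 0.0684 to 0.0879 without any single control. Without exposed replicate 1, rising genes at 0.08 mg/m3 at 1 week differed by 0.10 (adjusted p = 0.0293), and without exposed replicate 4, falling genes at 0.60 mg/m3 at 4 weeks differed by -0.04 (adjusted p = 0.039). With arrays centred on their median, the rise at 0.60 mg/m3 at 4 weeks was 0.02 (adjusted p = 0.364).

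Across exposure times, which share no controls, the genes called at 0.60 mg/m3 at both times held 649 higher and 448 lower at both and 576 in opposite directions, where independent calls would share 418 and 342. At 0.15 mg/m3 the counts were 175 higher, 111 lower and 79 opposite, where independent calls would share 87 and 71. At 0.08 mg/m3, 89 were higher, 20 lower and 502 opposite, where independent calls would share 191 and 91. At 0.04 mg/m3, 65 were higher, 138 lower and 171 opposite, where independent calls would share 169 and 73. The correlations of the changes across genes were 0.22, 0.27, -0.17 and 0.08 from the highest to the lowest concentration.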

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

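The tests of an age effect on the control difference and of a graded heart muscle response were chosen only after the results were seen, and so were the readings of the probe set test and of the mitosis comparison between exposure times. In 29 of 529 groups (5.5%) 1 array lay apart, by a gap to its nearest neighbour of more than 0.71 of the group's range, which chance gives in about 1 in 20 groups.

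Replicate 1 of 0.15 mg/m3 at 1 week lay apart most often, with Retnla at 10.36 against a mean of 12.95 in the other arrays (gap 0.91 of the range), Rrm2 at 7.94 against 9.43 (0.80), Melk at 5.36 against 7.27 (0.84) and Cdkn3 at 6.99 against 8.35 (0.84). Its replication and smooth muscle scores lay apart by 0.74 and 0.78. Among the other named genes the gaps were 0.71 for Ccna2 in the 1-week controls, 0.74 for Nell1 in replicate 5 of 0.04 mg/m3 at 1 week, and 0.77 for Per1 in replicate 5 of 0.60 mg/m3 at 1 week. They were 0.85 for Myoz2 in replicate 2 of 0.60 mg/m3 at 1 week, and 0.84 for Retnla in replicate 3 and 0.90 for Gsta3 in replicate 1 of the 4-week controls.

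Among list scores, skeletal muscle lay apart by 0.95 in replicate 3 of 0.04 mg/m3 (3.02 against 0.02) and by 0.92 in replicate 1 of 0.08 mg/m3 (6.11 against -0.01), both at 4 weeks. Adipocyte genes lay apart by 0.83 in replicate 4 of the 1-week controls (1.16 against 0.13). In the 4-week controls, goblet cell genes (0.78) and plasma cell genes (0.72) lay apart in replicate 1. In 0.60 mg/m3 at 4 weeks, type 2 cell (0.79), NRF2 target (0.71) and alveolar macrophage genes (0.76) lay apart in replicate 3. At 1 week of 0.60 mg/m3, smooth muscle (0.73) and chemokine genes (0.75) lay apart in replicate 1 and immediate early genes (0.87) in replicate 5. The other gaps were 0.73 for goblet cell genes in replicate 3 of 0.04 mg/m3 at 1 week, and 0.71 for them in replicate 2 of 0.08 mg/m3 at 4 weeks. They were 0.71 for immediate early genes in replicate 1 of 0.08 mg/m3 at 1 week, 0.78 for interferon genes in replicate 1 of 0.08 mg/m3 at 4 weeks, and 0.76 for alveolar macrophage genes both in replicate 5 of the 1-week controls and in replicate 2 of 0.15 mg/m3 at 1 week.

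The change at 0.60 mg/m3 differed between 4 weeks and 1 week, by the limma interaction test, in Ccl19 (3.0), Irf7 (2.91), Ptges (2.72), Dusp2 (2.68) and Zfp654 (2.65), and in Cxcr1 (-3.04), Hars1 (-2.83), Rrm2 (-2.59), Myoz2 (-2.53) and Gzma (-2.48). In the exposed arrays alone only Irf7 (1.39), Zfp654 (1.74), Cxcr1 (-1.40) and Rrm2 (-1.24) differed between the times, so the controls carry the other 6. The controls also differed by more than the exposed arrays in Irf7 (-1.53), Cxcr1 (1.64) and Rrm2 (1.35), and by less in Zfp654 (-0.91). The median differences of the lists that passed were 0.46 for MHC class II, 0.99 for T cells, 1.00 for smooth muscle, 0.81 for interferon genes, 0.75 for immediate early genes, -0.76 for replication, -0.98 for mitosis and -0.68 for xenobiotic metabolism. All had adjusted p = 0.971 with an estimated correlation.

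The 1-week and 4-week controls differed in 9873 genes. More smooth muscle or lymphoid tissue in the 1-week control dissections is argued against as the whole cause, since 49% of the oxidative phosphorylation, glycolysis and DNA repair genes, 24 of 49, changed at least 1.5-fold, 10 higher and 14 lower. An effect of 3 weeks more of age and handling that adds to every group alike is argued against by the slope of the time change at 0.60 mg/m3 on that of the controls, 0.32 (0.30 to 0.33 without 1 array), although the slope was 0.98 at 0.04 mg/m3. RNA or labelling quality of the 1-week control arrays stays open: 92.6% of second probe sets of a gene moved with the first, close to 93.3% at 0.60 mg/m3 at 4 weeks, which had been set beforehand to speak against quality, but a shift of whole transcripts on an array labelled from the 3' end would also move probe sets together. The leading axis within the 1-week controls, which held 54.2% of their spread, also lay along the control difference (cosine -0.74, against a size of 0.13 for the 4-week controls), so quality and group cannot be told apart, and neither processing date nor an age effect that differs with exposure was tested.

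Heart muscle genes were higher at 0.04 and 0.08 mg/m3 at 4 weeks, with medians of 1.91 and 1.31. A graded response to the concentration is argued against by a median of -0.05 at 0.60 mg/m3. A candidate explanation is that some dissections held more heart muscle of pulmonary veins. The residuals of the 13 genes correlated at 0.70 on average across the 4-week arrays (0.66 to 0.78 without 1 array), so these genes moved together within groups. Residuals leave out the group means, so they cannot decide what raised those means. Heart muscle scores ran from 1.47 to 2.16 over all 5 arrays at 0.04 mg/m3, against at most 0.318 in the controls. The rise was thus not limited to some arrays of that group. The brightest members were Myl7 (11.96 at 0.04 mg/m3 and 10.29 in controls), Myh6 (11.84 and 9.93) and Tnni3 (11.19 and 9.47), 8 of 13 members lay above the median of all genes in the controls, and 0 belonged to another list. A response seen at low concentrations alone was not tested and stays open.

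Mitosis genes were higher after 1 week of 0.15 and 0.60 mg/m3. RNA or labelling quality of the 1-week control arrays is argued against as the cause at 0.60 mg/m3, since the median against the 4-week controls was 1.52 (1.43 to 1.57 without 1 array), with 26 of 34 members higher. More cells in cycle after 1 week than after 4 weeks of exposure is a possible explanation that stays open. The median change between the 1-week and 4-week arrays at 0.60 mg/m3 was 0.50, which lay at the bound set beforehand, and it ranged from 0.40 to 0.59 without 1 array, with 19 members higher, 3 lower and quartiles of -0.09 and 1.19. Cell counts were not used here.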

How the results depend on the processing

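The tests with the axis position, the 4-week controls, the 25 arrays of 4 weeks, the list scores as covariates and the tissue lists without single arrays were chosen only after the results were seen, and the cause of a change was not tested except where the setting itself shows it.

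Requiring a change of at least 1.5-fold, which takes genes from each count by construction, left 385, 1883, 5469 and 5136 genes at 1 week and 464, 366, 200 and 740 at 4 weeks from the lowest to the highest concentration. It left 847 and 3181 of the differences between times at 0.04 and 0.08 mg/m3. With only the compared arrays modelled, the counts were 2274 and 3721 at 0.04 and 0.08 mg/m3 at 1 week, and 3902, 1101 and 3551 at 0.04, 0.15 and 0.60 mg/m3 at 4 weeks. With array weights they were 5283, 3440, 1994 and 4297 at 4 weeks and 3049 for the difference between times at 0.04 mg/m3. With arrays centred on their median they were 5481 at 0.04 mg/m3 at 1 week and 3011 for the difference between times. With the 25 arrays of 4 weeks alone they were 3082, 2364, 1092 and 3574, so the spread of the 1-week arrays lowers the counts at 4 weeks. With the axis position as a covariate, 5653 and 5958 genes were called at 0.15 and 0.60 mg/m3 at 1 week, 2823 and 4651 for the differences between times at 0.04 and 0.15 mg/m3, and 2495 between controls. Against the 4-week controls, 10973, 5729 and 6637 genes were called at 0.04, 0.15 and 0.60 mg/m3 at 1 week. With the muscle and B cell scores as covariates, 1, 6, 512 and 1898 genes were called at 4 weeks.

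A named gene is counted here and below once for each comparison that named it, and turned means an opposite sign, called or not. Of 87 named genes at 1 week, 55 kept their direction and call against the 4-week controls, 15 kept the direction without the call and 17 turned. The turned values were 0.17 for Gdf15, 1.00 for Stra6, 0.31 for Dact3, 1.38 for Des, 0.79 for Cnn1, 0.56 for Acta2, 1.10 for Actg2, -0.34 for Ankrd1, -0.20 for Myh6, 0.30 for Cfd, -0.49 for Slc39a8, 0.64 for Ccn1 and 0.68 for Maff at 0.60 mg/m3. They were 0.73 for Stra6 and 0.80 for Des at 0.15 mg/m3, and -0.50 for Ppp1r3b and 0.08 for Upk1a at 0.08 mg/m3. Among these, Gdf15, Dact3, Ankrd1, Myh6, Cfd, Slc39a8 and Upk1a were not called against the 4-week controls (limma, adjusted p from 0.0556 to 0.8). With the axis position as a covariate 75 of the 87 kept their call, 11 lost it and Slc39a8 at 0.60 mg/m3 (0.00) turned. Of the 20 named genes for the controls and for the difference between times at 0.60 mg/m3, 11 kept their call and 8 lost it. Between controls these were Hars1 (0.90), Ankrd1 (0.24), Fgg (0.26), Gzma (0.23), Stra6 (-0.93), Krt17 (-0.40) and Ptprcap (-1.18), and Igsf6 turned (-0.24). Between times it was Myoz2 (-1.43, adjusted p = 0.156). The axis lies along the control difference, so the covariate takes part of that difference away. The median size of the change in the 9873 genes went from 0.78 to 0.29 and the median standard error from 0.11 to 0.19. Of 128 named genes at 4 weeks, 112 kept their call with the muscle and B cell scores as covariates and 119 whichever array was left out, and all 128 with array weights, an intensity trend or the 25 arrays alone. Calls of Lamp3, Agr2, Spdef, Kdr, Tie1 and A2m were lost without single arrays. Without replicate 1 of 0.08 mg/m3 at 4 weeks the skeletal muscle list lost its call (adjusted p = 0.186), and the adipocyte, heart muscle, smooth muscle, B and T cell lists kept theirs at the preset correlation whichever array of that group was left out. With an estimated correlation the adjusted p of adipocyte, heart muscle, B and T cell lists was 0.17 or more each time, and called members fell to 1 for adipocytes and B cells and 0 for T cells. With an estimated correlation 17 of the 53 lists at 0.60 mg/m3 at 4 weeks and 6 at 1 week lost their call. The 53 include lists that had no call to lose. The 6 at 1 week were mitosis, replication, cholesterol synthesis, the unfolded protein and integrated stress response, immediate early genes and smooth muscle. Their adjusted p with an estimated correlation was 0.745 for smooth muscle and 0.573 for each of the others. With fry 6 lists at 4 weeks and 26 at 1 week gained a call.

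Response scores changed their side of the threshold with arrays centred on their median at 0.15 mg/m3 at 1 week (falling, -0.09, lost), 0.15 mg/m3 at 4 weeks (rising 0.06 and falling -0.06, both lost), 0.60 mg/m3 at 4 weeks (rising 0.02, lost, and falling -0.09, gained) and 0.08 mg/m3 at 4 weeks (falling 0.05, lost). Quantile normalization lost the falling score at 0.08 mg/m3 (0.09) and gained that at 0.60 mg/m3 (-0.06) at 4 weeks, and genes changed at least 1.5-fold lost the falling score at 0.15 mg/m3 at 1 week (-0.13). With each array left out in turn, counts ranged from 2261 to 4314 at 0.04 mg/m3 at 1 week (2261 without exposed replicate 4, 2327 without replicate 5). They ranged from 948 to 1944 at 0.04 mg/m3 at 4 weeks (948 without control replicate 2, 971 and 991 without exposed replicates 3 and 4) and from 606 to 1472 at 0.08 mg/m3 at 4 weeks (606 without exposed replicate 4, 683 without control replicate 2). Scores ranged from 0.07 to 0.10 for rising genes at 0.08 mg/m3 at 1 week, and for falling genes from -0.12 to -0.08 at 0.15 mg/m3 at 1 week, from 0.08 to 0.13 at 0.08 mg/m3 and from -0.04 to -0.02 at 0.60 mg/m3 at 4 weeks. Leaving out the dimmest 25% of genes, quantile normalization, the intensity trend and the use of all or the mean of a gene's probe sets left every count of called genes within 1.5 times its value. So did a replicate block (8731 genes at 0.60 mg/m3 at 1 week, 2284 at 4 weeks). The replicate numbers do not pair the arrays: arrays of the same number correlated from -0.49 to 0.39, and at most 2 of 5 correlated best with their own number. Genes near the background of the arrays, from 2.22 upwards, have compressed changes.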

Other observations

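The contrasts of 0.60 with 0.15 mg/m3 and all values of single arrays given here were chosen only after the results were seen.

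Between 0.15 and 0.60 mg/m3 at 4 weeks, interferon genes rose further, with 16 of 23 higher and 0 lower (median 0.50, adjusted p = 2.54e-25, and adjusted p = 0.0146 with an estimated correlation). Xenobiotic metabolism genes fell further, with 6 of 20 lower (median -0.29, adjusted p = 6.7e-12, and adjusted p = 0.0107 with an estimated correlation). Club cell genes did so too, with 4 of 10 lower (median -0.33, adjusted p = 1.92e-09, and adjusted p = 0.0158 with an estimated correlation). Complement genes had 4 of 16 higher (median 0.26, adjusted p = 1.73e-06, and adjusted p = 0.0122 with an estimated correlation), and MHC class II genes 6 of 10 higher (median 0.39, adjusted p = 1.2e-08), with adjusted p = 0.0625 with an estimated correlation. MHC class II genes did not follow the concentration at 4 weeks. Their mean score was -0.343 in the controls and 0.077, -0.053, -0.233 and 0.137 from the lowest to the highest concentration. At 1 week the contrast of 0.60 with 0.15 mg/m3 lowered xenobiotic metabolism, with 1 of 20 members called (median -0.23, adjusted p = 5e-12, and adjusted p = 0.011 with an estimated correlation).

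At 0.60 mg/m3 after 4 weeks, of 12 genes of transitional and injured alveolar epithelium 4 rose and 0 fell (4 adjusted over the list alone, adjusted p = 0.0345, and adjusted p = 0.224 with an estimated correlation). The list also lost its call with the 25 arrays of 4 weeks alone (adjusted p = 0.12). Among the risen genes were the protease receptor gene Plaur (1.20 ± 0.22) and the growth factor gene Areg (0.98). Monocyte genes had 6 of 13 higher (6 adjusted over the list alone, adjusted p = 0.000143) and dendritic cell genes 4 of 8 (5 adjusted over the list alone, adjusted p = 0.00567), each with adjusted p = 0.0962 with an estimated correlation. DNA repair genes had 7 of 20 higher and 1 lower (11 adjusted over the list alone, adjusted p = 0.00351, and adjusted p = 0.144 with an estimated correlation). Of 20 p53 targets 6 fell and 1 rose, including Gdf15 (-0.78), Phlda3 (-0.70) and the cell cycle inhibitor Cdkn1a (-0.53), and 3 of 6 red cell genes fell, including Alas2 (-0.86). Those lists did not pass the test, nor did circadian clock genes, in which 5 of 17 rose and 2 fell, with Bhlhe40 at 1.35 ± 0.14 and Npas2 at -0.84. These genes were named after their values were seen.

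In replicate 1 of 0.08 mg/m3 at 4 weeks, 205 genes lay at least 4-fold above the mean of the other 4 arrays of its group and 1 lay 4-fold below. They included genes of squamous epithelium, Krt13 at 12.73 against 3.98, Krt4 at 11.67 against 3.25, Loricrin at 12.56 against 3.71 and Sprr3 at 12.21 against 3.54. They also included genes of skeletal muscle, Acta1 at 12.90 against 4.55, Tnnc2 at 12.42 against 3.74 and Myl1 at 12.57 against 4.42.

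The number of called genes was compared with 100 splits of the same arrays into groups of the same sizes, the real split included. For 2 groups 126 splits are possible, so some were not tried. A share of 1 of 100 is the lowest possible here, and it makes chance unlikely without excluding it. At 4 weeks the real split gave the highest count at each concentration (1 of 100 splits). The counts were 1734 against at most 557 in other splits at 0.04 mg/m3, 1147 against 915 at 0.08 mg/m3, 470 against 29 at 0.15 mg/m3 and 2334 against 444 at 0.60 mg/m3. At 1 week the real split also gave the highest count at 0.04 mg/m3, with 3614 against 1079 (1 of 100). So it did at 0.15 mg/m3, with 9063 against 7576 (1 of 100), and at 0.60 mg/m3, with 8742 against 6991 (1 of 100). At 0.08 mg/m3 another split called more genes than the real one (6537 against 7014, 3 of 100), so chance is unlikely there but not excluded. For the differences between times the real split gave the highest count at 0.04 mg/m3, with 1613 against 566 (1 of 100). It also did so at 0.08 mg/m3, with 5964 against 5545 (1 of 100), and at 0.60 mg/m3, with 7616 against 4133 (1 of 100). For the difference at 0.15 mg/m3 another split called more genes (7629 against 7992, 2 of 100), so chance is again unlikely but not excluded. For the controls the counts were 9873 against 8582 (1 of 100).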
